A study of Mus musculus with 31 samples.

How the data were processed

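RNA from 31 samples of whole fetal mouse gonads was measured on Affymetrix 3′ expression arrays, 1 sample per array, from biotinylated cRNA made with a 3′ in vitro transcription kit, per the labels' protocols. Samples were grouped by the sex, age and genotype in the labels, which gave 12 groups of 1 to 3 arrays. The authors deposited log2 signals for 45101 probe sets, summarised by RMA per the submitters' processing notes. RMA corrects the background, normalises probes between arrays and limits the weight of outlying probes, so an overall shift of RNA content between samples is not visible in these values. The RMA version and the set of arrays normalised together are not given in the sources used here. Arrays have no read depth, and the number of arrays limits the precision.

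Probe sets were named from the platform annotation, which lists 35890 of them, 34958 with 1 gene symbol and 932 with several, while 9211 are not listed. Of the probe sets with 1 symbol 34754 matched the mouse gene table by gene ID, which updated 0 symbols. Probe sets with several symbols or none were not named or tested as genes. For each gene the probe set with the highest mean over the 31 arrays was used, which left 18194 genes, 9182 of them with 1 probe set. The gene table of assembly GRCm38.p6 served only for names, chromosomes and neighbouring genes.

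Changes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 1 mean per group over all 31 arrays and 19 residual degrees of freedom (prior degrees of freedom 3.999). Wild-type testes at 12 dpc have 1 array, which is taken to vary like the others. The 19 comparisons were Wv/Wv against wild type in each sex and age, testis against ovary in each genotype and age, the sex by genotype interaction at each age, 16 against 12 dpc in wild-type ovaries and testes, and the age by genotype interaction in each sex. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 within the comparison. Gene lists were tested with camera at a preset correlation of 0.01 and again with the correlation estimated from the data, and overlaps of calls with a one-sided Fisher's exact test. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

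The comparisons, tests, gene lists, rule for named genes and the first set of other settings were fixed before the data were examined. The 23 lists were germ cell, pluripotency and primordial germ cell, meiosis, male fetal germ cell and piRNA pathway, oocyte, Sertoli, Leydig and steroidogenesis, pregranulosa, interstitial stroma and hedgehog targets, smooth muscle and peritubular, endothelium, macrophage and leukocyte, mast cell and melanocyte, erythroid, mesonephros and kidney tubule, adrenal, neuron and glia, mitotic cell cycle, p53 target, retinoic acid, Kit and its neighbours, Y chromosome and housekeeping. Members without a probe set of 1 symbol, among them Nanos2 and Ddx3y, were not analysed here. The text names the 5 largest rises and 5 largest falls among called genes whose arrays do not overlap between the groups (for interactions, among called genes), up to 4 called members of each list with the largest change or the 2 largest where none was called, and a fixed set of marker genes of germ cells and somatic cells.

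The first set of other settings was array weights, genes of low signal left out (limit 5.705, passed by 14150 genes), every probe set tested, a 2-fold minimum, cyclic loess, centring on housekeeping genes, the labels' replicate number as a block, a trended robust variance prior, only the arrays compared in the fit, and each array left out in turn. Settings added after the data were seen were the array class as a term (class boundary at an SD of 2.25), wide-spread or narrow-spread arrays alone, wild-type testis 16 dpc array 1 left out of the whole fit, this together with the class term, and quantile normalization. The 27 pairs of arrays within groups had an SD of difference of at least 0.179 over genes, and no pair was taken for a duplicate.

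The tests were checked on simulated data with the real group means and 100 genes changed at each size among 18194. At a log2 change of 2 the share recovered was 68%, 86% and 87% for genotype in ovaries at 12, 14 and 16 dpc, 68%, 78% and 84% in testes, 47%, 82% and 84% for sex in wild type, 82%, 85% and 88% for sex in Wv/Wv, 46%, 48% and 66% for the sex by genotype interaction, 74% and 58% for age in ovaries and testes, and 51% and 43% for the age by genotype interaction. At a log2 change of 1 it was 21%, 44% and 34%, 9%, 24% and 38%, 7%, 37% and 37%, 25%, 29% and 35%, 0%, 5% and 8%, 36% and 13%, and 13% and 6%, in the same order. False calls numbered 1 to 12 per comparison.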

Results

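Gene expression was measured in whole fetal mouse gonads from wild-type embryos and from embryos homozygous for Wv, a point mutation in Kit that weakens the kinase activity of the receptor for stem cell factor. Primordial germ cells need Kit to survive and to reach the gonad, so the design sets gonads with a normal complement of germ cells beside gonads expected to hold few. Ovaries and testes were taken at 3 ages, 12, 14 and 16 dpc (days after mating), and each RNA sample was hybridised to 1 Affymetrix array. The 31 arrays fall into 12 groups. In wild-type ovaries there were 2, 3 and 3 arrays at 12, 14 and 16 dpc, in Wv/Wv ovaries 2, 3 and 3, in wild-type testes 1, 3 and 3, and in Wv/Wv testes 3, 2 and 3. The labels call the arrays of a group biological replicates without saying whether they came from separate embryos or pools, so p-values measure the spread between these samples, which may be partly technical. Values are log2 signals, changes are differences of group means with the standard error of the fit, and 18194 genes were tested. No detection calls were used here. Log2 changes carry no bound, so with lower-group arrays under 5.705, the 40th percentile of all values, they may not measure the size. A fold is then given as a lower bound with those arrays set to that limit. All arrays of the lower group read so, but for 2 of 3 for Dazl and Ddx4 in ovaries at 14 dpc and Dppa5a in testes at 12 dpc, and 1 of 2 for Cbln4 in wild type at 12 dpc.

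The 31 arrays were of 2 kinds. The SD of the log2 values over all probe sets was 2.33 to 2.39 on 21 arrays and 1.77 to 2.18 on the other 10, called narrow-spread arrays here. The 3′ minus 5′ difference of the Gapdh control probe sets was 2.01 ± 0.19 (SD, n = 21) on wide-spread and 0.70 ± 0.19 (SD, n = 10) on narrow-spread arrays. Narrow-spread arrays were all 3 wild-type ovaries at 16 dpc, Wv/Wv ovary 16 dpc array 2, wild-type ovary 14 dpc array 1, Wv/Wv ovary 14 dpc arrays 2 and 3, wild-type testis 16 dpc array 1, Wv/Wv testis 16 dpc array 1 and Wv/Wv testis 14 dpc array 2. Wild-type testis 16 dpc array 1 had the lowest SD, 1.77. Each count of genes is therefore followed by the count from a class-adjusted fit, chosen after the data were seen, in which the array class is a term and that array is left out. For wild-type ovaries at 16 dpc this fit assumes that the class shifts a gene by the same amount in every group.

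**Figure D1:**
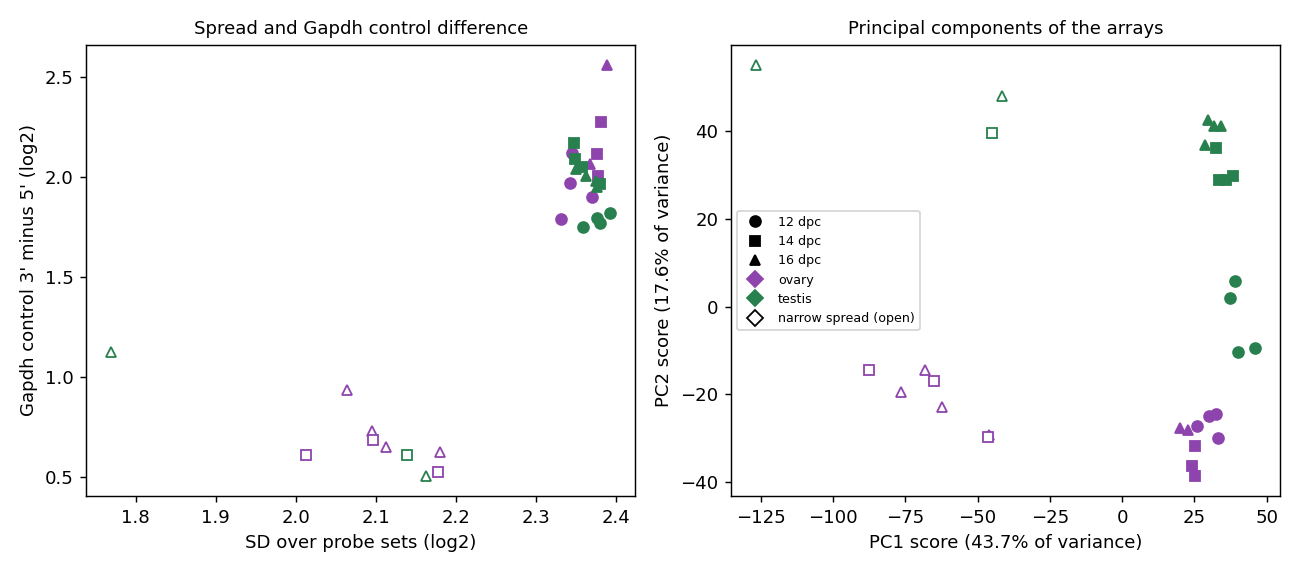
Left, SD of log2 values over probe sets against the Gapdh control 3′ minus 5′ difference for the 31 arrays; right, principal component 1 (43.7% of variance) against component 2 (17.6%), with open symbols for narrow-spread arrays. The 10 narrow-spread arrays have an SD of 1.77 to 2.18, the 21 others 2.33 to 2.39.

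Wild-type and Wv/Wv ovaries were compared first, to ask which transcripts depend on the germ cells. At 12 dpc, the transcripts lower in the mutant ovary were those of germ cells. Dazl, an RNA-binding protein that licenses germ cells for sexual development, was at least 7.22-fold lower (8.56 ± 0.37 in wild type and 3.65 ± 0.22 in Wv/Wv, SD, n = 2 each, adjusted p = 0.00338). Ddx4, the germ cell RNA helicase, fell by 4.61 ± 0.85 on the log2 scale, and Dppa5a, a pluripotency-associated RNA-binding protein, fell by 4.52 ± 0.79. The X-linked homeobox gene Rhox6 and the ribosomal protein paralogue Rpl39l fell by 4.37 ± 0.63 and 3.84 ± 0.54. In total 17 genes were called, 0 higher and 17 lower, and the class-adjusted fit called 34.

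Of 20 measured germ cell genes, 5 were called lower at 12 dpc and 13 when adjusted over the list alone, with a median change of −1.68 (camera adjusted p = 2.28e-06 with an estimated correlation). Of 23 pluripotency and primordial germ cell genes, 7 were lower, 14 adjusted over the list alone, with a median of −2.25 (adjusted p = 1.91e-07 with an estimated correlation). They included Pou5f1, the Oct4 pluripotency factor (−3.21 ± 0.62, adjusted p = 0.0359), Dppa4 (−3.39 ± 0.64) and Prdm14, a regulator of germ cell specification (−2.75 ± 0.51). Asz1, a component of the piRNA machinery, which silences transposons, fell by 2.94 ± 0.49, and the oocyte-list member Tcl1, an Akt coactivator, fell by 2.74 ± 0.44. No member of the 28-gene meiosis list was called at this age, 1 when adjusted over the list alone, and the median was −0.13 (adjusted p = 0.0695 with an estimated correlation). Stra8, the retinoic acid target that starts meiosis, stood at 5.24 ± 0.01 in wild type and 5.36 ± 0.01 in the mutant (SD, n = 2 each). Somatic markers showed no called difference: Foxl2, the transcription factor of granulosa cells, changed by −0.02 ± 0.30, Fst, which encodes the activin antagonist follistatin, by 0.20 ± 0.44 and Wnt4 by 0.09 ± 0.48. Of 12 mesonephros and kidney tubule genes 0 were called, and their median was 0.40 (adjusted p = 0.0291 with an estimated correlation). Kit itself was 9.17 ± 0.10 in wild type and 8.38 ± 0.34 in Wv/Wv (SD, n = 2 each; adjusted p = 1), and since Wv is a point mutation its transcript level does not check the labels. The count rested on few arrays: it was 0 without wild-type array 2, 0 without Wv/Wv array 1 and 1 without Wv/Wv array 2.

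At 14 dpc both germ cell and meiosis transcripts were lower in the mutant ovary. Dazl was at least 73.6-fold lower in Wv/Wv (12.52 ± 0.25 against 5.50 ± 1.78, SD, n = 3 each, adjusted p = 2.66e-08), Ddx4 at least 37.9-fold, and Stk31, a Tudor-domain germ cell protein, at least 24.2-fold. Mael, a piRNA factor, fell by 6.68 ± 0.47 and Slc25a31, a germ cell ADP/ATP carrier, by 6.61 ± 0.49. Sycp3, a lateral element protein of the synaptonemal complex, fell by 6.28 ± 0.46, Meioc, which keeps germ cells in meiotic prophase, by 5.76 ± 0.26, Tex12, a central element protein, by 5.68 ± 0.34, and Stra8 by 5.58 ± 0.52. The 5 largest rises among genes whose arrays did not overlap were smaller: Kcnip4, a potassium channel-interacting protein, rose by 2.58 ± 0.28 (adjusted p = 1.29e-06), Pax8, a transcription factor of tubular epithelium, by 1.53 ± 0.23, the atypical cadherin Fat4 by 1.45 ± 0.26, the calcium-binding protein Calb1 by 1.28 ± 0.32 and butyrylcholinesterase, Bche, by 1.23 ± 0.18.

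In total 795 genes were called at 14 dpc, 53 higher and 742 lower. The class-adjusted fit called 3743, 1069 higher and 2674 lower, including all 795. Other scalings gave 661 higher and 1387 lower with cyclic loess, 348 and 892 with housekeeping centring and 603 and 1157 with quantile normalization. Of the germ cell list 18 of 20 members were lower (19 adjusted over the list alone; median −3.83, adjusted p = 0.000304 with an estimated correlation), and of the meiosis list 22 of 28 (25 adjusted over the list alone; median −2.95, adjusted p = 0.0001 with an estimated correlation). The pluripotency list had 17 of 23 lower (18 adjusted over the list alone; median −2.43, adjusted p = 0.00248 with an estimated correlation), among them Sox2 (−5.41 ± 0.74), Pou5f1 (−4.28 ± 0.51) and the RNA-binding protein Lin28a (−4.41 ± 0.55). Among 19 genes of male fetal germ cells and the piRNA pathway 10 were lower, 11 adjusted over the list alone (median −1.02, adjusted p = 0.0161 with an estimated correlation), led by Asz1 (−4.77 ± 0.40), Piwil2 (−4.46 ± 0.40) and Mov10l1 (−3.63 ± 0.27). Of 20 oocyte genes 5 were lower, and 5 adjusted over the list alone, with a median of −0.15 (adjusted p = 0.196 with an estimated correlation). They included Sohlh2, a transcription factor of early oocytes (−3.83 ± 0.34), and Taf4b (−3.34 ± 0.29). Figla, which activates zona pellucida genes, fell by 1.76 ± 0.26, and Kit by 1.87 ± 0.54 (adjusted p = 0.0491).

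Outside the germ line at 14 dpc, 5 of 12 erythroid genes were lower, 8 adjusted over the list alone, with a median of −1.56 (adjusted p = 0.185 with an estimated correlation). Rhag, a component of the red cell Rh complex, fell by 3.21 ± 0.61, Klf1, the erythroid transcription factor, fell by 2.31 ± 0.47, and Slc4a1, the red cell anion exchanger, changed by −2.69 ± 0.63 (adjusted p = 0.0121). Of 22 mitotic cell cycle genes 6 were lower, 16 adjusted over the list alone, with a median of −0.97 (adjusted p = 0.223 with an estimated correlation). These included Bub1 (−2.85 ± 0.48), Cenpf (−2.00 ± 0.45) and Ccnb2 (−1.57 ± 0.32). Cpa3, a mast cell protease, fell by 2.11 ± 0.48. Dmrt1, which the Sertoli list holds but germ cells also express, fell by 3.40 ± 0.59. Hprt, on the housekeeping list, fell by 1.45 ± 0.33. No pregranulosa gene of 20 was called (median 0.08, adjusted p = 0.629 with an estimated correlation), and Foxl2 stood at 9.56 in both genotypes. The count of 795 was 361 without wild-type array 2, 1806 without Wv/Wv array 1, 460 without Wv/Wv array 2 and 404 without Wv/Wv array 3. On the 3 Wv/Wv arrays Dazl had an SD of 1.78 and Ddx4 of 1.88, against 0.25 and 0.53 in wild type.

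At 16 dpc meiosis and other germ cell genes were lower in the mutant ovary. Sycp3 was at least 68-fold lower (11.79 ± 0.25 in wild type and 4.22 ± 0.37 in Wv/Wv, SD, n = 3 each, adjusted p = 5.81e-11). Dazl fell by 6.96 ± 0.61, Slc25a31 by 6.79 ± 0.49, Mael by 6.73 ± 0.47 and Ddx4 by 6.34 ± 0.70. Tex12 fell by 6.76 ± 0.34 (at least 23.2-fold), Smc1b, the meiotic cohesin subunit, by 6.28 ± 0.30 and Sycp1, the transverse filament protein, by 6.15 ± 0.30. The largest rises were Kcnip4 (2.44 ± 0.28, adjusted p = 3.31e-06), then Hao2, a peroxisomal hydroxyacid oxidase (2.34 ± 0.44), the long non-coding RNA Rmst (2.27 ± 0.38), Nell1 (2.12 ± 0.53) and Cd83 (2.10 ± 0.51), the last 2 at 1.11 ± 0.25 and 1.33 ± 0.35 in the class-adjusted fit.

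In total 680 genes were called at 16 dpc, 253 higher and 427 lower. The class-adjusted fit called 3004, 1375 higher and 1629 lower, including 665 of the 680. The balance turned without Wv/Wv array 2 (1338 higher and 661 lower), with housekeeping centring (1500 and 741), with array weights (6477 and 4677) and without wild-type testis 16 dpc array 1 in the fit (1983 and 991), and was 1272 to 1262 with cyclic loess and 1034 to 1063 with quantile normalization. Of 28 meiosis genes 24 were lower, and 24 adjusted over the list alone, with a median of −3.70 (adjusted p = 6.68e-05 with an estimated correlation). The germ cell list had 14 of 20 lower; adjusted over the list alone 17 were lower and 1 higher, with a median of −3.44 (adjusted p = 0.00165 with an estimated correlation). Of 23 pluripotency genes 4 were lower, 13 adjusted over the list alone, with a median of −0.86 (adjusted p = 0.14 with an estimated correlation). They were Dppa5a (−3.05 ± 0.65), Zfp42 (−2.32 ± 0.36), Dppa3 (−2.14 ± 0.56) and Lin28a (−2.04 ± 0.55). Of the oocyte list 3 of 20 fell: Taf4b (−3.48 ± 0.29), Figla (−3.10 ± 0.26) and Sohlh2 (−2.79 ± 0.34). Of 19 piRNA-pathway genes 7 fell, 8 adjusted over the list alone, led by Mov10l1 (−4.09 ± 0.27; list median −0.36, adjusted p = 0.0251 with an estimated correlation). Stra8 fell by 4.26 ± 0.52, from 9.86 ± 1.77 in wild type (SD, n = 3), where array 2 lay apart from arrays 1 and 3 and nearer to 14 dpc.

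Few members of the somatic lists were called in the ovary at 16 dpc. Of 20 pregranulosa genes 1 was called, the signalling ligand Wnt5a (1.23 ± 0.32, adjusted p = 0.0341; 0.81 ± 0.15 in the class-adjusted fit), and the list median was 0.52 (adjusted p = 0.192 with an estimated correlation). Csf1r, the macrophage growth factor receptor, rose by 0.92 ± 0.23, Calb1 by 1.28 ± 0.32 and Dhrs3, a retinal reductase, by 0.72 ± 0.19. Of 14 mast cell and melanocyte genes 3 fell, 5 adjusted over the list alone (median −0.45, adjusted p = 0.313 with an estimated correlation). These were proteases of mast cells, another cell type that needs Kit: Cma1 (−2.68 ± 0.54), Cpa3 (−2.14 ± 0.48) and Tpsb2 (−1.12 ± 0.31), the last at −0.68 ± 0.24 in the class-adjusted fit (adjusted p = 0.0574). Of 12 erythroid genes 3 fell, 7 adjusted over the list alone (median −1.25, adjusted p = 0.0815 with an estimated correlation), namely Rhag (−3.91 ± 0.61), Klf1 (−3.04 ± 0.47) and Rhd (−2.43 ± 0.51). Of the mitotic list 3 of 22 fell, 4 adjusted over the list alone, with a median of −0.35 (adjusted p = 0.583 with an estimated correlation), led by Bub1 (−2.36 ± 0.48). Kit was 7.31 ± 0.66 in wild type and 8.49 ± 0.73 in Wv/Wv (adjusted p = 0.187). The count of 680 was 410, 400 and 341 without wild-type arrays 1, 2 and 3, and 288, 1999 and 314 without Wv/Wv arrays 1, 2 and 3.

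**Figure D2:**
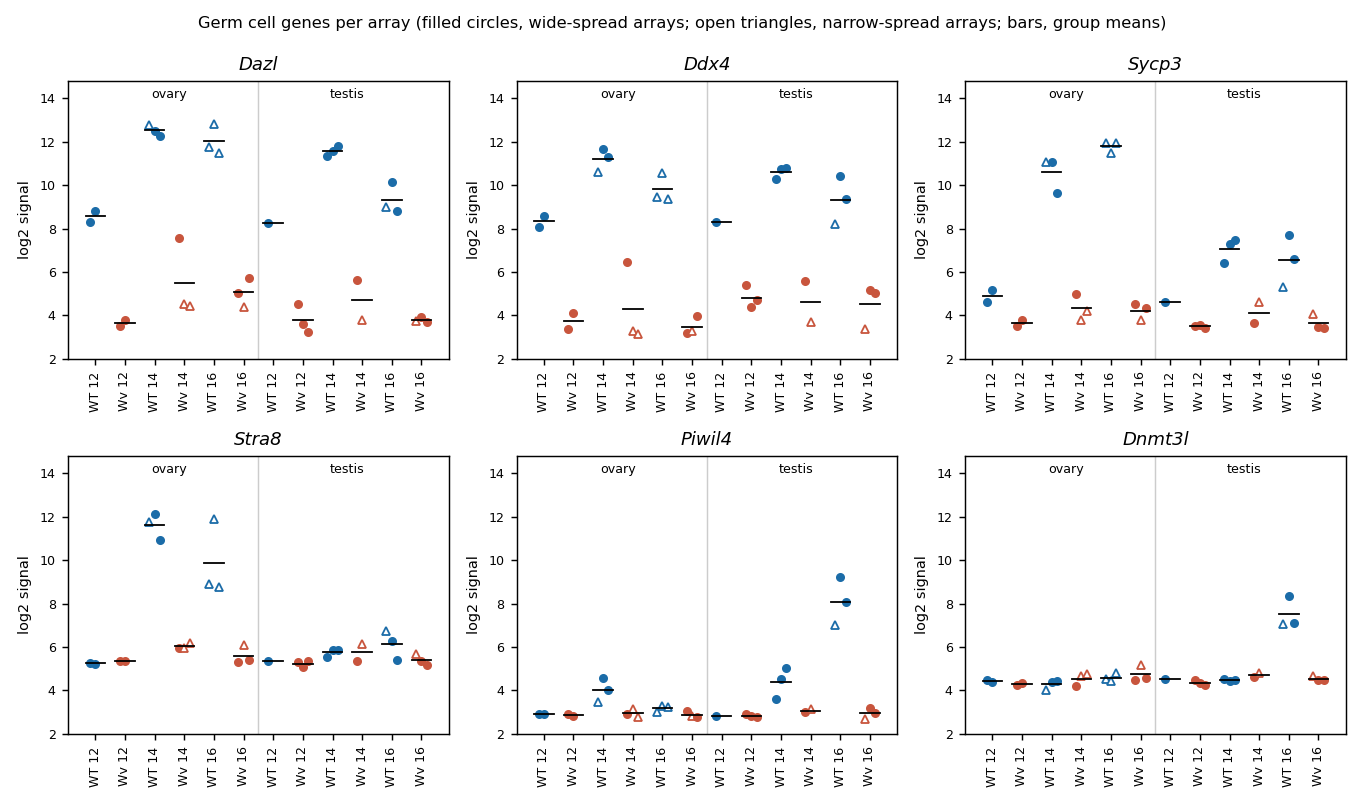
Log2 signal of Dazl, Ddx4, Sycp3, Stra8, Piwil4 and Dnmt3l on each array, by sex, age and genotype (blue wild type, red Wv/Wv); filled circles are wide-spread arrays, open triangles narrow-spread arrays and bars group means. Dazl in ovaries at 14 dpc has means of 12.52 in wild type and 5.50 in Wv/Wv, and Piwil4 in testes at 16 dpc 8.09 and 2.95.

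In the testis the same comparison also returned germ cell transcripts. At 12 dpc, with 1 wild-type array against 3, Dppa5a was at least 38.1-fold lower in Wv/Wv (11.29 against 5.78 ± 0.84, SD, n = 3, adjusted p = 0.0206). Rpl39l fell by 3.71 ± 0.62, the pluripotency-associated zinc finger gene Zfp42 by 3.24 ± 0.51, L1td1 by 2.91 ± 0.52 and Lefty2, a Nodal antagonist, by 2.87 ± 0.52. Prl8a2, a prolactin family gene of the placental decidua, was 8.73 on the single wild-type array and 3.67 ± 0.02 in Wv/Wv (SD, n = 3, adjusted p = 0.0026). It lay 2.75 above its highest value on the other 30 arrays, while the next gene, Prss12, lay 0.43 above. Whether that sample held tissue other than testis is not known, and it is the only wild-type testis at 12 dpc in every comparison by genotype, sex or age. These 6 genes were all that passed, 0 higher and 6 lower, and the class-adjusted fit called 22. Dazl (−4.46 ± 0.86, adjusted p = 0.0636) and Ddx4 (−3.49 ± 0.98, adjusted p = 1) did not pass.

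As a group, germ cell genes were lower in the mutant testis at 12 dpc: 1 of 20 was called, 10 adjusted over the list alone, and the median was −1.59 (adjusted p = 3.94e-05 with an estimated correlation). The pluripotency list had 2 of 23 lower, 14 adjusted over the list alone, and a median of −1.61 (adjusted p = 3.68e-06 with an estimated correlation). The piRNA-pathway list had 1 lower, 6 adjusted over the list alone, with a median of −0.34 (adjusted p = 0.000479 with an estimated correlation). No gene of the Sertoli list (24 genes, the supporting cells of the testis cord) was called, while its median was −0.53 (adjusted p = 0.0476 with an estimated correlation), and the 12 mesonephros and kidney tubule genes, with 0 called and 1 higher adjusted over the list alone, had a median of 0.73 (adjusted p = 0.00742 with an estimated correlation). Against the wild-type array, the Sertoli medians of Wv/Wv arrays 1, 2 and 3 were 0.28, −0.91 and −0.97 and the mesonephros medians −0.09, 1.02 and 1.28, so the 3 mutant samples did not move together. The count was 1 without Wv/Wv array 2 and 1 without Wv/Wv array 3.

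At 14 dpc Dazl was at least 58.4-fold lower in the mutant testis (11.57 ± 0.21, n = 3, against 4.71 ± 1.29, n = 2, SD, adjusted p = 1.58e-06). Stk31 fell by 6.14 ± 0.61, Ddx4 by 5.96 ± 0.78, Dppa5a by 5.64 ± 0.72 and Mael by 5.53 ± 0.52. Pmaip1, which encodes the pro-apoptotic protein Noxa and is a p53 target, fell by 4.57 ± 0.38 (adjusted p = 3.05e-07), the only called gene of 13 on the p53 list, whose median was −0.46 (adjusted p = 0.212 with an estimated correlation). In total 108 genes were called, 0 higher and 108 lower, and the class-adjusted fit called 172, including 107 of them.

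Of the germ cell list 13 of 20 genes were lower at 14 dpc, 16 adjusted over the list alone (median −3.40, adjusted p = 5.77e-05 with an estimated correlation). The pluripotency list had 16 of 23 lower by either adjustment, all genes or adjusted over the list alone (median −3.03, adjusted p = 5.77e-05 with an estimated correlation), among them Sox2 (−5.05 ± 0.82), Dppa4 (−4.76 ± 0.58), Dppa3 (−4.51 ± 0.62) and Pou5f1 (−4.15 ± 0.57). Of the piRNA-pathway list 9 of 19 were lower, 13 adjusted over the list alone (median −1.53, adjusted p = 0.000265 with an estimated correlation), led by Asz1 (−3.96 ± 0.45), Piwil2 (−3.30 ± 0.45) and Mov10l1 (−2.61 ± 0.30). Meiosis genes were lower in the mutant testis too: 11 of 28 were called, 14 adjusted over the list alone, with a median of −0.86 (adjusted p = 0.00145 with an estimated correlation). Tex11 fell by 3.04 ± 0.36, Hormad1, a chromosome axis protein, by 2.98 ± 0.41 and Sycp3 by 2.93 ± 0.51, from 7.05 ± 0.55 in the wild type (SD, n = 3). Tcl1 (−3.91 ± 0.40), Sohlh2 (−2.72 ± 0.38) and Taf4b (−1.49 ± 0.33) were the 3 of 20 oocyte-list genes called.

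Somatic lists of the testis held few calls at 14 dpc. Gng13, on the pregranulosa list, fell by 1.97 ± 0.37 and Lhx1, on the mesonephros list, by 2.19 ± 0.40. Of 24 Sertoli genes 0 were called (median 0.16, adjusted p = 0.965 with an estimated correlation). Amh, the hormone that removes the Müllerian duct, was 7.90 ± 0.44 in wild type and 9.86 ± 2.35 on the 2 mutant arrays (adjusted p = 0.848), a spread that leaves the difference open. Of 10 measured Leydig cell and steroid synthesis genes 0 were called (median 0.08, adjusted p = 0.969 with an estimated correlation), and Cyp17a1, the androgen-synthesis enzyme, stood at 13.41 ± 0.14 and 13.55 ± 0.14. Of the erythroid list 0 of 12 were called, 4 lower adjusted over the list alone, with a median of −0.99 (adjusted p = 0.24 with an estimated correlation). Without Wv/Wv array 2 the count was 62.

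At 16 dpc transcripts known from prospermatogonia, the male germ cells that have stopped dividing, were lower in the mutant testis. Mael was at least 20.7-fold lower (10.08 ± 1.60 against 3.55 ± 0.33, SD, n = 3 each, adjusted p = 1.2e-08) and Dazl at least 12.2-fold. Piwil4, the nuclear piRNA effector of prospermatogonia, fell by 5.15 ± 0.37, Morc1, which represses transposons in male germ cells, by 5.24 ± 0.61, Gtsf1 by 4.50 ± 0.45 and Dnmt3l, the cofactor of de novo DNA methylation, by 2.97 ± 0.25. Stk31 fell by 5.44 ± 0.54 (at least 6.19-fold), Slc25a31 by 5.32 ± 0.49 (at least 9.37-fold) and Dppa4 by 5.16 ± 0.52. In total 88 genes were called, 0 higher and 88 lower, and the class-adjusted fit called 181, including 86 of them.

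Of the germ cell list 15 of 20 were lower at 16 dpc, 16 adjusted over the list alone (median −2.84, adjusted p = 1.5e-05 with an estimated correlation), and of the piRNA-pathway list 9 of 19, 12 adjusted over the list alone (median −1.04, adjusted p = 1.06e-05 with an estimated correlation). Pluripotency genes were lower in 6 of 23 cases, 8 adjusted over the list alone (median −0.71, adjusted p = 0.0164 with an estimated correlation), among them Sall4 (−3.12 ± 0.66), Pou5f1 (−2.97 ± 0.51) and Lin28a (−2.62 ± 0.55). Of the meiosis list 9 of 28 were lower, 11 adjusted over the list alone (median −0.60, adjusted p = 0.00623 with an estimated correlation), with Tex12 (−3.56 ± 0.34), Sycp3 (−2.89 ± 0.46) and the cohesin subunit Stag3 (−2.39 ± 0.43). Sohlh1, a transcription factor of early germ cells, fell by 1.81 ± 0.26. No Sertoli gene of 24 was called (median 0.34, adjusted p = 0.865 with an estimated correlation) and no Leydig gene of 10 (median 0.66, adjusted p = 0.38 with an estimated correlation), while the median of all genes in this comparison was 0.12. The 13 housekeeping genes, with 0 called, had a median of 0.47 (adjusted p = 0.477 with an estimated correlation). The count was 51 without wild-type array 2 and 161 without wild-type array 3, and 1 when only the 6 arrays compared were fitted. Narrow-spread arrays alone, 1 of each genotype, gave 4482 higher and 1253 lower.

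The genes lower in Wv/Wv ovaries and in Wv/Wv testes were compared by overlap, over separate sets of arrays. At 12 dpc 4 genes were shared, where independent lists would share 0.00561. At 14 dpc 83 of the 108 genes lower in testes were also lower in ovaries, against 4.4 for independent lists, and at 16 dpc 45 of 88, against 2.07. In the class-adjusted fit 17, 132 and 77 genes were shared at 12, 14 and 16 dpc.

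**Figure D3:**
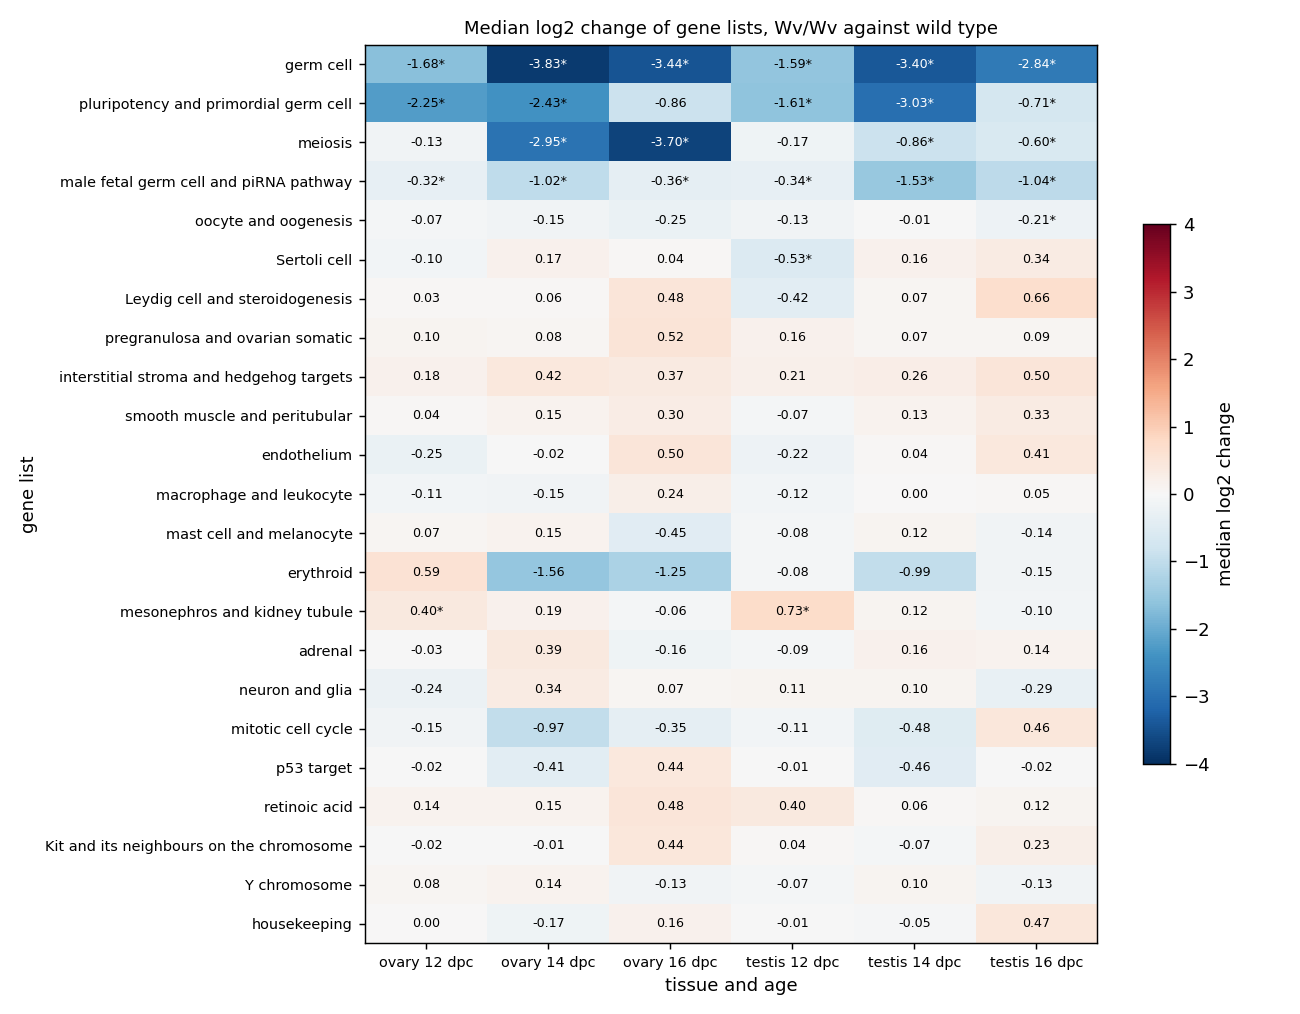
Heat map of the median log2 change, Wv/Wv minus wild type, of each of the 23 gene lists in ovary and testis at 12, 14 and 16 dpc; an asterisk marks a camera adjusted p under 0.05 with an estimated correlation. The germ cell list has medians from −1.59 to −3.83 with an asterisk in all 6 columns.

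Testes and ovaries were compared within each genotype, to ask which sex differences arise with and without a normal germ line. At 12 dpc in wild type, with 1 testis against 2 ovaries, the largest differences on the testis side after the Y-linked Eif2s3y (6.45 ± 0.84) and Kdm5d (6.22 ± 0.74) were in Sertoli cell genes and Prl8a2. Cbln4, a secreted synaptic organiser known from early Sertoli cells, was at least 28.3-fold higher in the testis (10.63 against 5.53 ± 0.52, SD, n = 2, adjusted p = 1.2e-06). The protease inhibitor Cst9 rose by 5.08 ± 0.65, the calcium-binding protein Tesc by 4.46 ± 0.75 and Dhh, the hedgehog ligand of Sertoli cells, by 4.31 ± 0.56. On the ovary side were Fst (−3.55 ± 0.54), the transcription factors Irx3 (−2.21 ± 0.36) and Sp5 (−2.07 ± 0.41), and Lypd6 (−1.68 ± 0.35). The Y-linked genes and Xist, the X-inactivation RNA (−5.86 ± 0.65), matched the sexes in the labels. Prl8a2 differed by 5.07 ± 0.72 and rested on the same single array as above. In total 46 genes were called, 39 higher in the testis and 7 lower, and the class-adjusted fit called 245. Without wild-type ovary array 1 there were 19 higher and 23 lower. Of 24 Sertoli genes 8 were higher, 15 adjusted over the list alone (median 1.87, adjusted p = 1.37e-06 with an estimated correlation), and of 20 pregranulosa genes 3 were lower, while adjusted over the list alone 10 were lower and 1 higher (median −1.16, adjusted p = 7.26e-06 with an estimated correlation). No germ cell gene was called by sex at this age, in a test that recovered 47% of simulated log2 changes of 2 (0 of 20 called by limma, 0 adjusted over the list alone; median −0.11, adjusted p = 0.894 with an estimated correlation).

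At 14 dpc steroid synthesis genes led the wild-type testis. Cyp11a1, the side-chain cleavage enzyme that starts steroid synthesis, was at least 94.3-fold higher than in the ovary (12.26 ± 0.18 against 4.94 ± 0.27, SD, n = 3 each, adjusted p = 3.64e-13) and Cyp17a1 was 130-fold higher. Star, which moves cholesterol into mitochondria, rose by 4.47 ± 0.32 and Hsd3b1 by 3.35 ± 0.39. The glutathione transferase Gsta2 was 6.02 ± 0.42 higher. In the ovary the largest differences were in Stra8 (−5.86 ± 0.52), Fst (−5.41 ± 0.36), Calb1 (−5.37 ± 0.32) and Meioc (−5.28 ± 0.26), besides Xist (−6.04 ± 0.43). In total 1079 genes were called, 576 higher and 503 lower in the testis, and the class-adjusted fit called 3270, 1412 higher and 1858 lower. The balance also turned with the class term alone (922 and 1330), on wide-spread arrays (1742 and 2062), with array weights (1959 and 2178), over every probe set (657 and 740) and without wild-type ovary array 1 (388 and 419).

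In wild type at 14 dpc 13 of 24 Sertoli genes were higher in the testis; adjusted over the list alone 18 were higher and 1 lower (median 1.58, adjusted p = 0.000632 with an estimated correlation), with Cst9 (5.93 ± 0.43), Dhh (4.62 ± 0.37) and Sox9 (2.05 ± 0.50) among them. Of 10 Leydig genes 8 were higher, 9 adjusted over the list alone (median 3.01, adjusted p = 0.000203 with an estimated correlation). Hedgehog targets of the interstitium rose: of 13 interstitial genes 4 were called, 8 adjusted over the list alone (median 0.90, adjusted p = 0.0246 with an estimated correlation), namely Hhip (4.17 ± 0.47), Gli1 (3.28 ± 0.34), Ptch1 (2.29 ± 0.61) and Pdgfra (1.47 ± 0.39). Smooth muscle genes were higher for 5 of 10, and 5 adjusted over the list alone (median 0.89, adjusted p = 0.00909 with an estimated correlation), led by Acta2 (1.76 ± 0.26). Of 20 pregranulosa genes 15 were lower in the testis and 1 higher, 16 and 1 adjusted over the list alone (median −1.96, adjusted p = 3.83e-06 with an estimated correlation), with Irx3 (−4.88 ± 0.24), Runx1 (−3.37 ± 0.37) and Foxl2 (−3.14 ± 0.24) among the lower. The adrenal markers Cyp11b1, the 11β-hydroxylase (3.19 ± 0.29), and Mc2r, the ACTH receptor (2.02 ± 0.34), were higher in the testis, 2 of 9 on that list (median 0.29, adjusted p = 0.228 with an estimated correlation). Cyp26b1, which degrades retinoic acid in the fetal testis, rose by 3.14 ± 0.29 and Crabp1, a retinoic acid-binding protein, was lower (−2.16 ± 0.51). These were the 2 of 12 retinoic acid genes called (median −0.25, adjusted p = 0.952 with an estimated correlation).

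Meiosis genes also differed by sex at 14 dpc in wild type, 23 of 28 lower in the testis, 24 adjusted over the list alone (median −1.78, adjusted p = 0.000203 with an estimated correlation), among them Sycp3 (−3.54 ± 0.46). Rec8, the meiotic cohesin, was also among them (−4.12 ± 0.28), but it differed by −3.68 ± 0.31 in Wv/Wv gonads too. Lefty2 (4.87 ± 0.37), Lefty1 (2.50 ± 0.34) and Nodal (2.07 ± 0.22), ligand and antagonists of a pathway active in male germ cells, were higher in the testis, and Pmaip1 rose by 5.23 ± 0.34. Dazl (−0.95 ± 0.61, adjusted p = 0.61) and Ddx4 (−0.61 ± 0.70, adjusted p = 0.918) showed no called difference.

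At 16 dpc the wild-type sexes differed in 1755 genes, 819 higher and 936 lower in the testis. The class-adjusted fit called 2928, 1452 higher and 1476 lower, including 1274 of these. Cyp11a1 was at least 96.7-fold higher (12.30 ± 0.96 against 4.41 ± 0.18, SD, n = 3 each, adjusted p = 7.06e-14), followed by Cyp17a1 (7.37 ± 0.30), Gsta2 (5.91 ± 0.42), Cst9 (5.80 ± 0.43) and the alcohol dehydrogenase Adh1 (5.24 ± 0.41). On the ovary side the largest differences were in Calb1 (−5.63 ± 0.32), Ugt8a, a galactosyltransferase (−5.52 ± 0.34), Fst (−5.36 ± 0.36), Xist (−5.32 ± 0.43) and Smc1b (−5.29 ± 0.30). Prospermatogonial genes were higher in the testis for 5 of 19 members and lower for 1, with 6 and 1 adjusted over the list alone (median 0.37, adjusted p = 0.215 with an estimated correlation), led by Piwil4 (4.93 ± 0.37), Tdrd9 (3.82 ± 0.35) and Dnmt3l (2.93 ± 0.25). Of the meiosis list 25 of 28 were lower, and 25 adjusted over the list alone (median −2.61, adjusted p = 0.000201 with an estimated correlation). Sertoli genes were higher for 13 of 24, and Leydig genes for 8 of 10, with medians of 1.78 and 3.25. Of 12 erythroid genes 4 were lower in the testis (median −1.08, adjusted p = 0.17 with an estimated correlation), namely Rhag, Klf1, Gata1 and the transferrin receptor Tfrc (−1.76 ± 0.35). Without wild-type testis array 1, the array of lowest SD, the count was 4773, 3175 higher and 1598 lower. The balance also turned with housekeeping centring (2016 and 753), array weights (6099 and 4229), cyclic loess (1886 and 1571) and a 2-fold minimum (608 and 548).

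In Wv/Wv gonads the sex differences of somatic cells were also found, and those of meiosis genes mostly were not. At 12 dpc 68 genes were called, 50 higher and 18 lower in the testis (72 and 44 with cyclic loess), and the class-adjusted fit called 406. Cbln4 was at least 18.5-fold higher (9.92 ± 0.79, n = 3, against 4.99 ± 0.14, n = 2, SD, adjusted p = 6.12e-09), Cst9 rose by 4.54 ± 0.49 and Cbln1 by 4.28 ± 0.44, while Fst (−3.58 ± 0.41), Irx3 (−1.99 ± 0.27) and Foxl2 (−1.45 ± 0.27) were lower. Of 24 Sertoli genes 10 were higher (15 adjusted over the list alone; median 1.56, adjusted p = 4.03e-06 with an estimated correlation). Without Wv/Wv ovary arrays 1 and 2 in turn the count was 34 and 23, and without Wv/Wv testis array 1 it was 38.

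At 14 dpc 671 genes differed between Wv/Wv testes and ovaries, 423 higher and 248 lower, and the class-adjusted fit called 2682. Housekeeping centring gave 455 higher and 490 lower. Cyp11a1 was at least 109-fold higher in the testis (12.48 ± 0.13, n = 2, against 4.64 ± 0.15, n = 3, SD, adjusted p = 9.54e-13), and Cst9 (5.64 ± 0.49), Cbln1 (5.67 ± 0.44) and Amh (3.41 ± 0.81) were also higher. Calb1 (−5.91 ± 0.36), Irx3 (−5.47 ± 0.27), Fst (−5.47 ± 0.41) and Gng13 (−4.97 ± 0.37) were lower. Of 24 Sertoli genes 14 were higher (17 higher and 1 lower adjusted over the list alone; median 2.17, adjusted p = 0.000365 with an estimated correlation), of 10 Leydig genes 8 (9 adjusted over the list alone; median 3.21, adjusted p = 0.000168 with an estimated correlation), and of 20 pregranulosa genes 14 were lower and 1 higher (15 and 1 adjusted over the list alone; median −2.02, adjusted p = 6.14e-07 with an estimated correlation). Of 28 meiosis genes 1 was called, Rec8 (−3.68 ± 0.31), and the median was −0.11 (adjusted p = 0.621 with an estimated correlation). Rec8 stood at 9.72 ± 0.15 in Wv/Wv ovaries and 10.55 ± 0.20 in wild-type ovaries (SD, n = 3 each). Lefty2 was still higher in the mutant testis (2.89 ± 0.41). The count was 330 without Wv/Wv testis array 1 and 422 without array 2.

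At 16 dpc 1266 genes differed, 689 higher and 577 lower, and the class-adjusted fit called 3728. The balance turned with housekeeping centring (729 and 986), array weights (2516 and 3038), wide-spread arrays alone (1684 and 2072) and without Wv/Wv ovary array 2 (533 and 648). Cyp11a1 was at least 151-fold higher (12.94 ± 0.07 against 4.58 ± 0.18, SD, n = 3 each, adjusted p = 3.91e-14) and Calb1 at least 38.4-fold lower. Sertoli genes were higher for 15 of 24 and lower for 1 (median 1.71), Leydig genes higher for 8 of 10 (median 3.30), and pregranulosa genes lower for 16 of 20 and higher for 1 (median −2.30). Mitotic genes were higher in the mutant testis for 10 of 22, 17 adjusted over the list alone (median 1.21, adjusted p = 0.136 with an estimated correlation), after 4 and 14 at 14 dpc (median 1.04, adjusted p = 0.186 with an estimated correlation). Aurkb (1.53 ± 0.41), Kif11 (1.51 ± 0.37) and Birc5 (1.44 ± 0.27), genes of the mitotic spindle and cytokinesis, were among them. In wild type 0 of these 22 were called at 14 dpc. At 16 dpc 1 was lower, Rrm2 (−1.32 ± 0.36, and −0.32 ± 0.25 in the class-adjusted fit, adjusted p = 0.47). Counts of calls do not test a difference. At 16 dpc the genotype median of these genes in testes was 0.46, but −0.12 without wild-type testis array 1. Lyz2, the macrophage lysozyme, was higher in the mutant testis (1.48 ± 0.35), 1 of 15 macrophage genes called (median −0.15, adjusted p = 0.977 with an estimated correlation), and Tubb3 (1.93 ± 0.40) was 1 of 10 neuron and glia genes (median −0.11, adjusted p = 0.977 with an estimated correlation). Endothelial genes had 0 of 16 called, 2 higher adjusted over the list alone (median 0.20, adjusted p = 0.952 with an estimated correlation). Of 20 genes around Kit on its chromosome 2 were called, Lnx1 (7.15 ± 0.30 in testes and 8.15 ± 0.35 in ovaries, SD, n = 3 each, adjusted p = 0.000654) and Dcun1d4 (−0.55 ± 0.16), with a list median of −0.04 (adjusted p = 0.977 with an estimated correlation). Of 6 Y chromosome genes 3 were higher (median 0.94, adjusted p = 0.00835 with an estimated correlation).

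**Figure D4:**
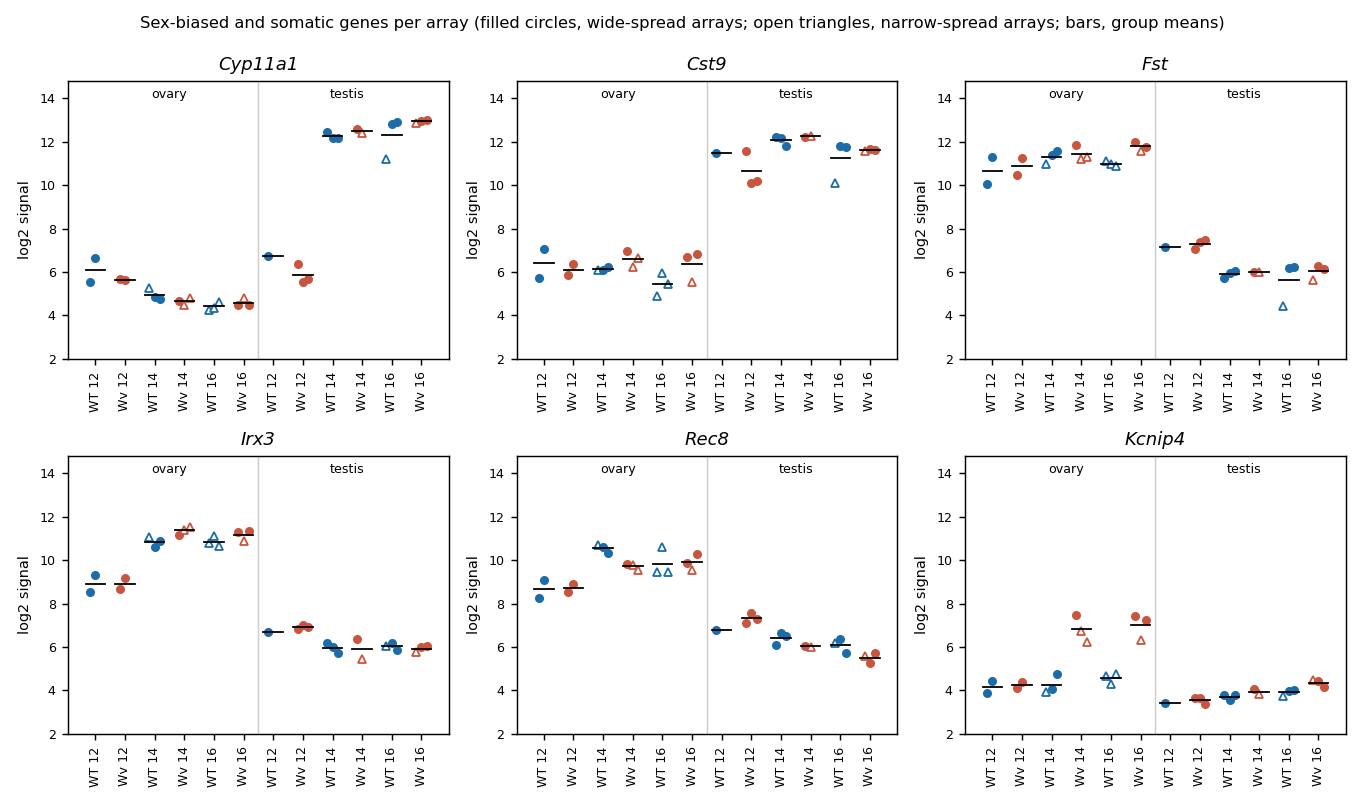
Log2 signal of Cyp11a1, Cst9, Fst, Irx3, Rec8 and Kcnip4 on each array, by sex, age and genotype (blue wild type, red Wv/Wv); filled circles are wide-spread arrays, open triangles narrow-spread arrays and bars group means. Cyp11a1 in Wv/Wv gonads at 16 dpc has means of 12.94 in testes and 4.58 in ovaries.

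The sex differences of the genotypes were compared by overlap, again over separate arrays. Of genes higher in the testis, 35 were shared at 12 dpc, 318 at 14 dpc and 432 at 16 dpc, where independent lists would share 0.107, 13.4 and 31. Of genes higher in the ovary, 6, 188 and 269 were shared, against 0.00693, 6.86 and 29.7.

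Whether the effect of Wv differed between the sexes was tested as a sex by genotype interaction, the change in testes minus the change in ovaries. At 12 dpc limma called 0 genes, with 16 at an unadjusted p under 0.05; array weights called 4, wide-spread arrays alone 2 and the class-adjusted fit 1. At 14 dpc 50 genes were called, 42 positive and 8 negative, and the class-adjusted fit called 351. Stra8 led (5.58 ± 0.78, adjusted p = 0.000569), followed by Meioc (5.17 ± 0.39), 1700013H16Rik (4.67 ± 0.35), the germ cell surface protein Tex101 (4.47 ± 0.67) and Rhox6 (4.19 ± 0.77), all lower in mutant ovaries. Of 28 meiosis genes 7 were positive, 20 adjusted over the list alone (median 1.51, adjusted p = 9.26e-05 with an estimated correlation). Negative terms, where the mutant testis fell more, were Pmaip1 (−4.52 ± 0.50), the Y-linked ubiquitin-activating enzyme gene Uba1y (−3.89 ± 0.80), the homeobox genes Otx2 (−3.15 ± 0.38) and Hesx1 (−2.44 ± 0.43), and Nodal (−2.33 ± 0.33). Kcnip4 was negative (−2.34 ± 0.43), with a rise in mutant ovaries and levels of 3.71 ± 0.14 and 3.94 ± 0.18 (SD, n = 3 and 2) in wild-type and mutant testes. No difference between the sexes was called for Dazl, with a term of 0.16 ± 0.91 (adjusted p = 1). The count was 29 and 33 without wild-type ovary array 2 and Wv/Wv ovary array 3, 33 and 32 without wild-type testis arrays 1 and 2, and 28 and 17 without Wv/Wv testis arrays 1 and 2.

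At 16 dpc 148 genes were called, 118 positive and 30 negative, and the class-adjusted fit called 520, including 136 of these. The balance turned with housekeeping centring (118 positive and 169 negative) and array weights (3241 and 5748), and 10 of 100 drawn splits of the arrays, the real one included, gave at least 148 genes. Positive terms were led by Ugt8a (5.27 ± 0.49, adjusted p = 3.97e-07), Terb1, which ties telomeres to the nuclear envelope in meiosis (5.23 ± 0.47), Smc1b (5.10 ± 0.42), Meioc (4.99 ± 0.37) and Sycp3 (4.68 ± 0.65). Of the meiosis list 20 of 28 were positive, 24 adjusted over the list alone (median 2.60, adjusted p = 0.000133 with an estimated correlation). Negative terms were led by Piwil4 (−4.85 ± 0.53), Morc1 (−4.46 ± 0.87), the small GTPase Rrad (−3.98 ± 0.43), Tdrd9 (−3.75 ± 0.49) and Dppa4 (−3.70 ± 0.74), with Dnmt3l (−3.15 ± 0.36) and Sohlh1 (−1.96 ± 0.37). Somatic lists had 0 called members for Sertoli, Leydig and pregranulosa genes (medians 0.21, 0.00 and −0.40). The count was 91 without Wv/Wv ovary array 3 and 93 without Wv/Wv testis array 1.

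Development from 12 to 16 dpc was followed in wild-type gonads. In the ovary 1398 genes changed, 548 higher and 850 lower at 16 dpc, while the class-adjusted fit called 2137, 1281 higher and 856 lower, including 944 of these. The balance also turned with the class term alone (1116 and 455) and without 12 dpc array 1 (197 and 157). Meiosis genes and Tex101 of the germ cell list rose most: Sycp3 by 6.89 ± 0.51 (4.90 ± 0.40, n = 2, to 11.79 ± 0.25, n = 3, SD, adjusted p = 3.9e-09), Tex12 by 6.27 ± 0.38, Sycp1 by 6.26 ± 0.33, Tex101 by 6.24 ± 0.50 and Meioc by 5.67 ± 0.29, with 24 of 28 on the list called by all genes and 24 adjusted over the list alone (median 3.04, adjusted p = 0.000538 with an estimated correlation). Pluripotency genes were lower for 10 of 23; adjusted over the list alone 13 were lower and 2 higher (median −1.53, adjusted p = 0.261 with an estimated correlation), among them Sox2 (−3.27 ± 0.82) and Tfap2c (−3.13 ± 0.70). Shisa3 (−6.59 ± 0.56), the embryonic globin Hbb-bh1 (−5.73 ± 0.52), Cdh10 (−4.30 ± 0.34), the nuclear receptor Nr2f1 (−4.26 ± 0.62) and Hoxa9 (−4.11 ± 0.89) fell most. In the class-adjusted fit Nr2f1 and Hoxa9 changed by −3.12 ± 0.43 and −2.30 ± 0.60, less than the embryonic globin Hba-x (−4.78 ± 0.72). Foxl2 (2.04 ± 0.27), Gng13 (3.73 ± 0.37) and Lgr5 (1.98 ± 0.27) rose, among 4 higher and 1 lower of 20 pregranulosa genes. Neurofilament and growth cone genes Nefm (−4.08 ± 0.53), Nefl (−3.63 ± 0.52) and Gap43 (−2.55 ± 0.28) fell, among 5 of 10 neuron and glia genes (6 adjusted over the list alone; median −1.44, adjusted p = 0.0554 with an estimated correlation). All 3 arrays at 16 dpc were narrow-spread and both at 12 dpc wide-spread, so array class and age coincide here. The count was 722 and 665 without 16 dpc arrays 1 and 3, and 354 and 538 without 12 dpc arrays 1 and 2.

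In the wild-type testis, with 1 array at 12 dpc, 300 genes changed, 172 higher and 128 lower, and the class-adjusted fit called 1226. Steroid synthesis and prospermatogonial genes rose: Cyp17a1 by 7.51 ± 0.42 (6.01 to 13.52 ± 0.69, SD, n = 3, adjusted p = 9.18e-11), Cyp11a1 by 5.56 ± 0.46, Piwil4 by 5.29 ± 0.53 and Mael by 4.83 ± 0.66. The muscle LIM protein Pdlim3 rose by 4.86 ± 0.59. Of 10 Leydig genes 6 rose (7 adjusted over the list alone; median 2.87, adjusted p = 0.000949 with an estimated correlation) and of 19 piRNA-pathway genes 7 (adjusted over the list alone 11 higher and 1 lower; median 0.93, adjusted p = 0.00447 with an estimated correlation). Hbb-bh1 (−6.64 ± 0.65), Shisa3 (−6.20 ± 0.71), Hba-x (−4.71 ± 0.87), Prl8a2 (−4.31 ± 0.68) and Sox2 (−4.01 ± 1.04) fell most. Without 16 dpc array 1 the count was 474, and limma called 0 (304 at an unadjusted p under 0.05) when only the 4 arrays compared were fitted. Centring on housekeeping genes gave 511 higher and 101 lower, the class term alone 463 and 476, and leaving out 16 dpc arrays 2 and 3 in turn 126 and 155, and 159 and 163.

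Whether the change with age differed in Wv/Wv was tested as an age by genotype interaction. In the ovary 101 genes were called, 5 positive and 96 negative, and the class-adjusted fit called 488. Array weights gave 5392 positive and 3253 negative. Tex12 (−6.57 ± 0.53, adjusted p = 7.98e-08), Hemgn, an erythroid nuclear protein (−6.40 ± 1.34), Sycp3 (−6.32 ± 0.73), Tex101 (−6.16 ± 0.70) and Sycp1 (−6.07 ± 0.47) had the lowest terms. Hemgn rose in wild type (6.98 to 9.80) but not in Wv/Wv (8.00 to 4.42). Of 28 meiosis genes 21 had negative terms (23 adjusted over the list alone; median −3.01, adjusted p = 2.6e-05 with an estimated correlation). Positive terms were L1td1 (3.31 ± 0.58), Kcnip4 (2.36 ± 0.45), Nanog (1.87 ± 0.36), Bche (1.57 ± 0.28) and the steroid dehydrogenase Akr1c18 (1.46 ± 0.34). The count was 64 without Wv/Wv 12 dpc array 2. In the testis 12 genes were called, 2 positive and 10 negative, and the class-adjusted fit called 29. The negative terms were led by Piwil4 (−5.18 ± 0.65, adjusted p = 0.000768), Mael (−4.76 ± 0.81), Gtsf1 (−4.21 ± 0.79), Tdrd9 (−4.20 ± 0.60) and the X-linked RNA export factor Nxf2 (−3.86 ± 0.55), and the positive ones were Prl8a2 (4.83 ± 0.83) and Lefty2 (3.54 ± 0.64). The count was 7, 6 and 7 without Wv/Wv 16 dpc arrays 2 and 3 and Wv/Wv 12 dpc array 2, and limma called 0 (104 at an unadjusted p under 0.05) when only the arrays compared were fitted.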

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

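All tests of explanations in this part were chosen after the result was seen. The interaction terms were planned and test directly whether an effect differs between sexes or ages.

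The genotype effect differed between testes and ovaries for 50 genes at 14 dpc and 148 at 16 dpc. At 14 dpc the terms were highest for Stra8 (5.58), Meioc (5.17), 1700013H16Rik (4.67), Tex101 (4.47) and Rhox6 (4.19), and lowest for Pmaip1 (−4.52), Uba1y (−3.89), Otx2 (−3.15), Hesx1 (−2.44) and Kcnip4 (−2.34). At 16 dpc they were highest for Ugt8a (5.27), Terb1 (5.23), Smc1b (5.10), Meioc (4.99) and Sycp3 (4.68), and lowest for Piwil4 (−4.85), Morc1 (−4.46), Rrad (−3.98), Tdrd9 (−3.75) and Dppa4 (−3.70). The change from 12 to 16 dpc differed between genotypes for 101 genes in ovaries, with L1td1 (3.31), Kcnip4 (2.36), Nanog (1.87), Bche (1.57) and Akr1c18 (1.46) at the upper end and Tex12 (−6.57), Hemgn (−6.40), Sycp3 (−6.32), Tex101 (−6.16) and Sycp1 (−6.07) at the lower. In testes it differed for 12 genes, among them Prl8a2 (4.83), Lefty2 (3.54), Piwil4 (−5.18), Mael (−4.76), Gtsf1 (−4.21), Tdrd9 (−4.20) and Nxf2 (−3.86).

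The 31 arrays split into 21 with a wide and 10 with a narrow spread. Degraded RNA on the narrow-spread arrays would raise their 3′ minus 5′ difference of Gapdh. It was lower by 1.31, which argues against degradation there as the cause. Wild-type testis 16 dpc array 1 had a difference of 1.12, against at most 0.94 on the other 9, and the highest of the 10 for Actb too, which leaves poorer RNA on that array open. The narrow minus wide profile was alike in the 6 groups that hold both classes. The lowest correlation over genes, which are not independent replicates, was 0.666 among 15 pairs (median 0.814). A processing batch common to all groups would give this, but the classes were set by the spread itself. Any cause that narrows the spread could give alike profiles, so the correlation does not decide, and the labels name no batch. Each of these 6 groups is of 1 sex, age and genotype, which argues against any of these as the whole cause, although all 8 arrays at 12 dpc were wide-spread.

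Wild-type ovary 16 dpc array 2 lay apart from arrays 1 and 3. Over 169 genes that changed between 14 and 16 dpc in testes, its median distance from wild-type ovary 14 dpc array 1 was 0.127 ± 0.044 (SE over genes), against 0.479 ± 0.11 and 0.517 ± 0.11 for arrays 1 and 3. Its SD of 2.18 was also the nearest to that array's, but with the part along the profile of the array classes removed the distances were 0.122 ± 0.044 against 0.50 ± 0.10 and 0.554 ± 0.11, which argues against quality of that kind as the whole cause. Tissue from a stage nearer 14 dpc, a younger embryo or another label, may account for it, while quality of another kind stays open.

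Of 12 erythroid genes 5 were lower in Wv/Wv ovaries at 14 dpc, but the list, with a median of −1.56, did not pass with an estimated correlation (adjusted p = 0.185). Less blood carried over would lower the 3 embryonic globins too, and their median was 0.261 against −2.06 for the other 9 members, which argues against it. Array class as the whole cause is argued against by list medians of −1.33 in the class-adjusted fit, −1.75 on wide-spread arrays (1 Wv/Wv against 2 wild-type arrays) and −0.71 on narrow-spread arrays (2 against 1). In testes of the same age the 9 members had a median of −1.45, as fewer definitive erythroid precursors in Wv/Wv embryos, where Kit also acts in blood formation, could give. The medians of −2.06 in ovaries and −0.22 in testes at 16 dpc, and 0.72 and −0.17 at 12 dpc, do not show that fall in both sexes at the other ages, so the hypothesis stays open.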

How the results depend on the processing

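Settings added after the data were seen are named above. The cause of a moved count was not tested except where a fit holds fewer arrays. Counts moved more than directions. Over all alternatives 0 called changes of named genes reversed, 13778 stayed on their side of the threshold, 1056 lost the call and 137 gained it. Of list results 7337 stayed on their side, 431 lost the call, 184 gained it and 29 reversed by camera's direction in the original or the alternative call. Among results without a call on either side, 333 gene changes and 692 list medians changed sign. By contrast, the germ cell list stayed lower in Wv/Wv in all 6 genotype comparisons under every alternative run. Counts of genes lay within 1.5 times the values of the report in 212 cases and moved further in 173. Signal over background limits the low end: 14150 genes passed the limit of 5.705, and leaving out the others moved 0 counts by more than 1.5 times, as did the trended robust variance prior.

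The report counted 17, 795 and 680 genes for genotype in ovaries at 12, 14 and 16 dpc, and 6, 108 and 88 in testes. For sex it counted 46, 1079 and 1755 in wild type and 68, 671 and 1266 in Wv/Wv. The sex by genotype term had 0, 50 and 148. Age gave 1398 in wild-type ovaries and 300 in testes, and the age by genotype term 101 in ovaries and 12 in testes. Array weights gave 64, 11158 and 11154 for genotype in ovaries at 12, 14 and 16 dpc, 28 and 696 for genotype in testes at 12 and 16 dpc, 163, 4137 and 10328 for sex in wild type at 12, 14 and 16 dpc, 919 and 5554 for sex in Wv/Wv at 12 and 16 dpc, 4, 77 and 8989 for the sex by genotype term at 12, 14 and 16 dpc, 9824 for age in wild-type ovaries, 1022 for age in wild-type testes, 8645 for the age by genotype term in ovaries and 57 for the age by genotype term in testes. Cyclic loess gave 2048 and 2534 for genotype in ovaries at 14 and 16 dpc, and 166 and 154 in testes. At 12, 14 and 16 dpc it gave 76, 1902 and 3457 for sex in wild type and 116, 1251 and 2074 in Wv/Wv. The sex by genotype term had 1, 84 and 507 with it at these ages. Age gave 3004 in wild-type ovaries and 612 in testes, and the age by genotype term in ovaries 214. Housekeeping centring gave 1240 and 2241 for genotype in ovaries at 14 and 16 dpc, 183 for genotype in testes at 16 dpc, 2769 for sex in wild type at 16 dpc, 32 and 287 for the sex by genotype term at 14 and 16 dpc and 612 for age in wild-type testes. Quantile normalization gave 1760 and 2097 for genotype in ovaries at 14 and 16 dpc, 145 for genotype in testes at 16 dpc, 3420 for sex in wild type at 16 dpc, 1136 for sex in Wv/Wv at 14 dpc, 1 and 497 for the sex by genotype term at 12 and 16 dpc, 2542 for age in wild-type ovaries, 522 for age in wild-type testes and 194 for the age by genotype term in ovaries. The class term alone gave 30, 1862 and 1560 for genotype in ovaries at 12, 14 and 16 dpc, 15 and 180 for genotype in testes at 12 and 16 dpc, 146, 2252 and 5751 for sex in wild type at 12, 14 and 16 dpc, 217, 1668 and 2587 for sex in Wv/Wv at 12, 14 and 16 dpc, 1, 180 and 1332 for the sex by genotype term at 12, 14 and 16 dpc, 939 for age in wild-type testes and 278 for the age by genotype term in ovaries. The class-adjusted fit gave 34, 3743 and 3004 for genotype in ovaries at 12, 14 and 16 dpc, and 22, 172 and 181 in testes. For sex it gave 245, 3270 and 2928 in wild type and 406, 2682 and 3728 in Wv/Wv. The sex by genotype term had 1, 351 and 520 in this fit. Age gave 2137 in wild-type ovaries and 1226 in testes, and the age by genotype term 488 and 29. Leaving wild-type testis 16 dpc array 1 out of the whole fit gave 27, 1906 and 2974 for genotype in ovaries at 12, 14 and 16 dpc, 11 for genotype in testes at 12 dpc, 1632 and 4773 for sex in wild type at 14 and 16 dpc, 107 and 1098 for sex in Wv/Wv at 12 and 14 dpc, 1 for the sex by genotype term at 12 dpc, 4633 for age in wild-type ovaries and 474 for age in wild-type testes. Wide-spread arrays alone gave 48 and 2043 for genotype in ovaries at 12 and 14 dpc, 30, 171 and 173 for genotype in testes at 12, 14 and 16 dpc, 182 and 3804 for sex in wild type at 12 and 14 dpc, 649, 1320 and 3756 for sex in Wv/Wv at 12, 14 and 16 dpc, 2 and 94 for the sex by genotype term at 12 and 14 dpc and 1932 for age in wild-type testes. Narrow-spread arrays alone, a smaller set, gave 371 and 315 for genotype in ovaries at 14 and 16 dpc, 5735 for genotype in testes at 16 dpc, 7384 for sex in wild type at 16 dpc, 538 for sex in Wv/Wv at 16 dpc and 3228 for the sex by genotype term at 16 dpc. Fitting only the arrays compared, with fewer degrees of freedom, gave 2, 212 and 312 for genotype in ovaries at 12, 14 and 16 dpc, 1 for genotype in testes at 16 dpc, 4 and 213 for sex in wild type at 12 and 16 dpc, 5 and 160 for sex in Wv/Wv at 12 and 14 dpc, 1, 17 and 48 for the sex by genotype term at 12, 14 and 16 dpc, 7113 for age in wild-type ovaries, 0 for age in wild-type testes and 0 for the age by genotype term in testes. A 2-fold minimum, which can only remove genes, gave 444 for genotype in ovaries at 16 dpc and 1156 for sex in wild type at 16 dpc. Testing every probe set gave 1064 for genotype in ovaries at 16 dpc. Leaving out 1 array at a time gave ranges of 0 to 20, 361 to 1806 and 288 to 1999 for genotype in ovaries at 12, 14 and 16 dpc, 1 to 6, 62 to 105 and 51 to 161 for genotype in testes at 12, 14 and 16 dpc, 1177 to 4773 for sex in wild type at 16 dpc, 23 to 71 and 330 to 741 for sex in Wv/Wv at 12 and 14 dpc, 17 to 62 and 91 to 192 for the sex by genotype term at 14 and 16 dpc, 354 to 1192 for age in wild-type ovaries, 281 to 474 for age in wild-type testes, 64 to 119 for the age by genotype term in ovaries and 6 to 17 for the age by genotype term in testes.

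In the class-adjusted fit the genes lower in Wv/Wv of both sexes numbered 17, 132 and 77 at 12, 14 and 16 dpc, those higher in testes of both genotypes 133, 898 and 939 and those higher in ovaries of both 58, 660 and 728. The 2-fold minimum left 176 genes higher in ovaries of both genotypes at 16 dpc. Replicate numbers in the labels were also used as a replicate block, although same-numbered arrays did not deviate together (138 pairs, median r 0.006, range −0.849 to 0.847, 37 over 0.1), so they share only a number. The replicate block gave 24, 687 and 533 genes for genotype in ovaries and 9, 102 and 91 in testes, moved 0 counts of the 19 comparisons by more than 1.5 times, and left 3 genes higher in ovaries of both genotypes at 12 dpc. Another scaling moved the balance of higher and lower genes. Beside the splits given with each comparison, 2 and 10 became 1 and 14 for the age by genotype term in testes with housekeeping centring. Housekeeping centring shifted the median of all genes by 0.28 and −0.14 for genotype in ovaries at 14 and 16 dpc, 0.10 and −0.41 in testes, 0.15 for sex in wild type at 16 dpc, −0.25 and −0.12 for sex in Wv/Wv at 14 and 16 dpc, −0.17 and −0.27 for the sex by genotype term, 0.34 and 0.54 for age in ovaries and testes, and −0.18 and −0.47 for the age by genotype term. Cyclic loess shifted it by −0.11 for genotype in testes at 16 dpc and 0.10 for age in testes. In testes at 16 dpc the genotype median of mitotic genes was 0.46, against −0.031 with array weights, −0.12 without wild-type testis array 1, 0.037 in the class-adjusted fit and −0.033 on wide-spread arrays. There housekeeping genes went from 0.47 to −0.053 with cyclic loess and −0.067 without that array, mast cell genes from −0.14 to 0.087 without it, and adrenal genes, at 0.14, gained a call upward at 0.20 without it and 0.23 on wide-spread arrays. The age by genotype median of mitotic genes in testes went from 0.51 to −0.10 without that array, and the age median of housekeeping genes in testes from −0.51 to 0.11 with cyclic loess. With the class term mast cell medians went from 0.47 to 0.0013 for age in ovaries and from 0.12 to −0.14 for genotype in testes at 14 dpc. On narrow-spread arrays the sex medians in wild type at 16 dpc went from −0.31 to 0.15 for mast cell and from 0.30 to −0.75 for mitotic genes. At 12 dpc single ovary arrays decided several lists. Without wild-type array 1 the genotype medians went from 0.03 to −0.14 for Leydig and from 0.10 to −0.36 for pregranulosa genes, and the sex by genotype medians from −0.01 to 0.43 for pregranulosa and from 0.09 to −0.25 for interstitial genes. Without wild-type array 2 the interstitial genotype median went from 0.18 to −0.22 and the age by genotype median of pregranulosa genes from 0.44 to −0.035. The interstitial median was −0.034 without Wv/Wv array 1. Without Wv/Wv array 2 the erythroid genotype median went from 0.59 to −0.046 and its sex median in Wv/Wv from −0.45 to 0.27. With 1 array left out at a time, the genotype medians ranged at 12 dpc in ovaries from −0.14 to 0.28 for Leydig, −0.36 to 0.36 for pregranulosa, −0.22 to 0.57 for interstitial and −0.046 to 1.26 for erythroid genes, and at 16 dpc in testes from −0.32 to 0.087 for mast cell, −0.11 to 0.30 for adrenal, −0.12 to 0.70 for mitotic and −0.067 to 0.71 for housekeeping genes. Sex by genotype medians at 12 dpc ranged from −0.22 to 0.43 for pregranulosa and −0.25 to 0.32 for interstitial genes, the sex median of erythroid genes in Wv/Wv at 12 dpc from −1.25 to 0.27, and age by genotype medians from −0.035 to 0.81 for pregranulosa genes in ovaries and −0.10 to 0.80 for mitotic genes in testes.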

Other observations

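The test of X-linked genes was planned before its result was seen, and the counts over other splits of the arrays were chosen after it.

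From 12 to 16 dpc in wild-type ovaries, called genes of several lists moved both ways, with array class and age coinciding. Of 10 Leydig genes Hsd3b1, a steroid dehydrogenase, rose (3.76 ± 0.44) and Cyp11a1 was lower (−1.70 ± 0.37; 1 and 1 adjusted over the list alone; list median 0.27, adjusted p = 0.616 with an estimated correlation). Of 14 mast cell and melanocyte genes 2 rose, 1 in the class-adjusted fit, led by the chymase Cma1 (3.04 ± 0.60), and Dct was lower (−1.75 ± 0.39; 3 higher and 1 lower adjusted over the list alone; median 0.47, adjusted p = 0.45 with an estimated correlation). Of 12 retinoic acid genes 1 rose, Aldh1a1 (2.78 ± 0.45), and 5 were lower, among them Rarb (−2.83 ± 0.60; 2 higher and 5 lower adjusted over the list alone; median −0.96, adjusted p = 0.45 with an estimated correlation). Of 12 erythroid genes 3 rose, among them Klf1 (2.66 ± 0.53), and the embryonic globins Hbb-bh1 and Hba-x were lower (−5.73 ± 0.52 and −4.10 ± 0.69; 6 higher and 3 lower adjusted over the list alone; median 1.07, adjusted p = 0.616 with an estimated correlation). Prl8a2 read 8.73 on the single wild-type testis array at 12 dpc and at most 4.89 on 28 others. On wild-type and Wv/Wv testis 16 dpc array 1 it read 5.98 and 5.08. At 12 dpc Wv/Wv testis array 1 was closer to the wild-type array (SD of difference over genes 0.262) than arrays 2 and 3 (0.38 and 0.379). The germ cell medians of the 3 mutant arrays against it were −1.45, −1.18 and −1.70.

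Both X chromosomes are active in XX germ cells, so a hypothesis was that their absence lowers X-linked transcripts in Wv/Wv ovaries. In the class-adjusted fit the median change of 466 X-linked genes minus that of 13646 autosomal genes was −0.0192 at 14 dpc (one-sided permutation p = 0.19, adjusted p = 0.38 over 6 comparisons), against 0.0545 in testes. In the fit of the report it was −0.0884 (permutation p = 0.0024, adjusted p = 0.014). At 12 dpc it was −0.0131 in ovaries in both fits, in the predicted direction (one-sided permutation p = 0.056 and 0.059, adjusted p = 0.17 class-adjusted and 0.088 in that of the report). In ovaries at 16 dpc the value went the other way, 0.0319 in the class-adjusted fit and 0.145 in that of the report. In testes, where no fall was predicted, it was −0.0273 at 12 dpc in both fits (adjusted p = 0.046 class-adjusted and 0.022 in that of the report) and −0.0553 at 14 dpc in that of the report (adjusted p = 0.022). The hypothesis stays open.

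The counts of genes were set against other splits of the same arrays. Comparisons of 3 against 3 arrays have 10 splits, too few for a share under 0.05. At 14 dpc 2 of 10 splits gave as many genes for genotype in ovaries, the real one with 795 and another with 4000, which put the 3 narrow-spread arrays on one side; with the class term the real count was 1862. For genotype at 16 dpc 1 of 10 splits gave as many, with 680 in ovaries and 88 in testes against at most 1 in another split of either. For sex in wild type 1 of 10 did at 14 dpc, 1079 against 0, and 2 of 10 at 16 dpc, 1755 against 5683. For sex in Wv/Wv at 16 dpc 1 of 10 did, 1266 against 0. For the sex by genotype term at 16 dpc 10 of 100 drawn splits, the real one included, reached 148 genes, the highest 7767. Chance is thus not excluded for that count, and splits with many times the real count point to a structure of the arrays.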
